A study of Mus musculus with 23 samples.

How the data were processed

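The series measured mRNA levels in whole mouse spleen after infection with Listeria monocytogenes strain EGDe, an intracellular bacterium. Per the labels, female mice 4 to 5 weeks old were infected intravenously with a dose below the lethal one, and total RNA of infected spleens was hybridised on 2-colour arrays against RNA pooled from 6 non-infected control animals. There were 23 arrays, of which 12 carried the infected RNA on Cy5 and 11 on Cy3. They cover 7 times: 4 h (2 arrays), 1 d (2), 2 d (4), 3 d (3), 4 d (4), 5 d (4) and 9 d (4). Arrays are named by time and replicate, so that 2 d 3 is replicate 3 of 2 d. Other hours and days that the labels' design mentions were not analysed here. The labels call the arrays of a time point technical replicates, so each time point was taken as 1 sample, and the pool was the only control.

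The deposited value table holds 1 log2 ratio per probe and array for 20205 probes, of which 12799 to 16166 are filled per array. The scanner, background correction, normalization and filter that the authors used are not given in the sources used here, and neither is the direction of the ratio. The values were read as log2 because filled values other than the extreme ones below reach at most 9.97 in size on both sides of 0. The direction taken here, infected over pool on every array, is likely but not stated, as the labels list the infected RNA as channel 1 on every array whatever its dye. Ratios taken in dye order would change sign between dyes. Ctrb1 at 1 d stood at -7.23 on Cy5 and -7.16 on Cy3, and Alb at 2 d between 7.04 and 7.41 on all 4 arrays, and the acinar list had the same sign on both dyes at all 7 times. This speaks for 1 order on the arrays, although Alb at 5 d stood at 4.05 on Cy5 and -3.05 on Cy3. Whether that order is infected over pool or the inverse is not settled by the values. Array medians as deposited ran from -0.961 to 1.154. Of the 327035 filled cells, 9454 (2.89%) held values of 15.58 to 18.36 in size, separated from all others, as a ratio takes when 1 channel is at a floor. These were treated as missing.

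Probes were named through the platform annotation: 13852 had 1 gene symbol, 0 had several and 6353 had no listed gene here. Entrez identifiers matched for 13849 of the named probes, 0 symbols were updated, and 9802 distinct symbols resulted. Probes of 1 symbol were averaged.

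The rows of the deposited table do not all refer to the same probe. The pattern of filled and empty cells of an array was correlated with that of the other arrays. As deposited, the arrays of 4 h, 1 d and 2 d gave r of 0.009 to 0.024. A hidden Markov model (shifts from -10 to 446 rows, 3 passes, probability of a change 1e-09 per row) placed most of their rows 432 to 435 rows away, and after realignment r was 0.225 to 0.329. At 9 d, replicate 4 was shifted by 1 row after row 6007, and r went from 0.141 to 0.255. Rows with a posterior under 0.95 were treated as missing. The pattern of the 4 d arrays was weak (r of 0.017 to 0.084). The model placed 4 d replicates 1, 2 and 4 at a shift of 0, with 0 rows left out. Their r was 0.045, 0.076 and 0.084, against at most 0.024, 0.034 and 0.039 at nearby shifts. For 4 d replicate 3 the pattern was too weak for most rows, and it was placed by its values. Its Spearman correlation with arrays of the same dye was highest at a shift of 0 for the first rows (0.205) and of 1 for the last (0.176). Rows after 5956 were thus moved by 1, and 1001 rows around the change were left out. On simulated shifts of 4 arrays, 99.99% to 100.0% of placed rows were right. Whether the annotation follows the rows of 3 d, 5 d and 9 d was checked on 5481 pairs of probes with the same symbol: their patterns correlated with r of 0.078 at the annotated rows against at most 0.042 elsewhere over 1201 shifts. For the realigned 4 h, 1 d and 2 d arrays on their own this check found nothing (0.018 against 0.055 elsewhere), so their gene names rest on the match of their rows to the other arrays. The realignment was chosen after the data were examined, and the results with rows as deposited are given with the alternatives.

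For each gene and time point, ratios were averaged within each dye and then over both dyes, so that dye bias cancels. Only probes with a value on both dyes at every time point entered the tests, which left 3157 probes of 2156 genes. Time points were put into 4 windows: early (4 h and 1 d), days 2 to 3, days 4 to 5, and day 9. limma 3.58.1 in R 4.3.3 fitted the window means (lmFit, eBayes, two-sided, 3 residual and 3.52 prior degrees of freedom). The ratio was tested against 0 in each window, as were differences between successive windows and, by a moderated F, any difference between windows. Benjamini-Hochberg adjustment was applied over genes, with a threshold of 0.05. Day 9 is 1 time point and is assumed to vary like the others. The p-values measure the spread between the time points of a window, pooled over the windows that hold 2 time points. They leave out the spread between control animals, and nothing in the labels gives the spread between infected animals at one time. True change within a window, such as from 4 h to 1 d, thus counts as error in every window. Ctrb1, at 1.42 at 4 h and -7.19 at 1 d, has a wide SE throughout, although it was at -6.19 at 2 d and -6.77 at 3 d. The number of arrays limits the precision.

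Gene lists were tested with camera (preset correlation 0.01, again with an estimated correlation, and with fry), adjusted over the lists of a comparison. In all, 31 lists were written before the data were examined, for spleen cell types, responses to infection, cell cycle and housekeeping functions, and tissues that could be taken along with a spleen. The tests, windows, most alternatives and the rule for named genes were also fixed before the data were examined. Lists with under 5 measured genes were only described, and 16 were tested. A list of 34 hepatocyte genes was added after liver genes had been seen among the highest, leaving those out, and a list of 25 pancreatic islet genes was added before its result was seen.

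Single time points have 1 sample and no test. Their values use every probe with both dyes at that time, so lists are larger than in the windows. The SD over arrays is technical. A list's median was set among the medians of 10000 random lists of the same size, and values below the 2.5 or above the 97.5 percentile are said to lie outside the random lists. This describes these arrays and is no p-value.

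Genes named are, per window, the 8 largest rises and falls past the threshold with 1 sign at all its time points and on both dyes, up to 2 members of each list, 4 and 4 for differences and for 4 h and 1 d; where none passed, the genes with the smallest p, given as not past it. Genes from the array-level fit and time courses fall outside this rule and were chosen after their values were seen. H2, Gzm, Ly6 and haemoglobin family probes may cross-hybridise.

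Alternatives fixed beforehand were centring and scaling of arrays, plain means, stricter and looser rules on missing values, other windows, a spline of time, weights, robust moderation, every probe on its own, arrays as replicates with a dye term (with and without the replicate number as a block), and leaving out each time point or array. Rows as deposited, floor values kept, Cy3 arrays with the sign turned, days 3, 4, 5 and 9 only, the looser missing-value rule for lists, and lists without acinar and hepatocyte genes were added after seeing the data.

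The gene test was tried on simulated data for days 2 to 3 over 2156 genes: in 10 runs it found 4.18% of genes changed by a log2 of 1, 60% of those changed by 2 and 94.4% of those changed by 4, with 52 false calls. A list of 12 genes shifted by a log2 of 1 was found in 20 of 20 simulations, and 3 of 380 unshifted lists were called. The simulated genes were drawn independently, so these counts do not cover lists whose members are correlated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.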

Results

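Spleen RNA from mice infected with Listeria monocytogenes was compared with pooled RNA of non-infected spleens at 7 times from 4 h to 9 d, to follow the transcriptional response of the whole organ over the infection. There were 23 arrays, 2 to 4 per time point, and 1 sample per time point. The arrays were noisy. Pairs of arrays with the same dye and time correlated across genes with a median r of 0.092 (0.042 to 0.317), and pairs with the same time but opposite dyes with a median r of 0.036 (-0.173 to 0.165). For pairs with the same dye but different times the median r was 0.026 (-0.084 to 0.183, 112 pairs). Arrays of 1 time on opposite dyes thus correlated hardly more than arrays of different times. Genes are not independent replicates in these values. The median technical SD of a gene ran from 0.373 at 1 d to 1.54 at 3 d on the log2 scale. At 3 d only 37.9% of genes had the same sign on both dyes. The array medians there were 1.073 and 0.827 on Cy5 and -0.787 on Cy3. This offset of whole arrays enters both that share and the SD at 3 d. Positive ratios mean higher in infected spleen, a direction that is likely but not stated in the labels.

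**Figure D1:**
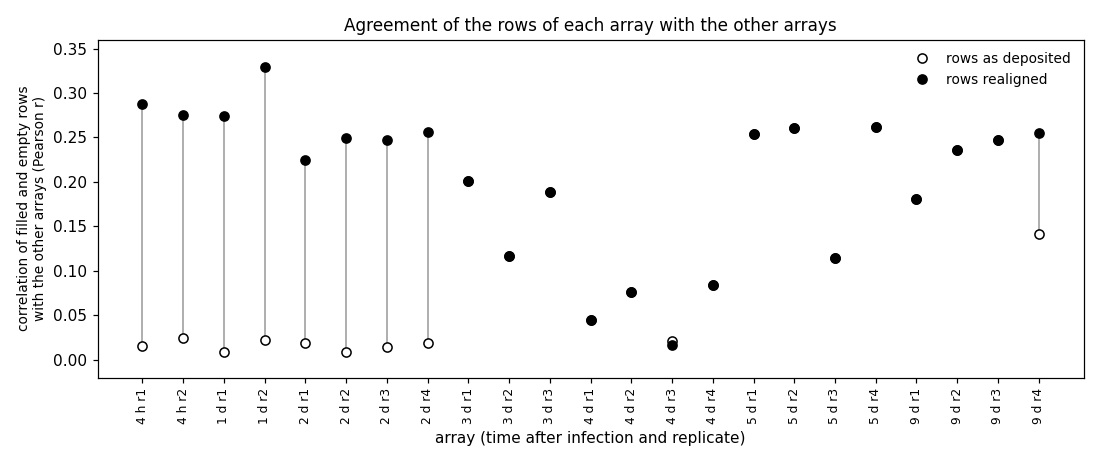
For each array (x axis, time and replicate), the Pearson correlation of its filled and empty rows with those of the other arrays, with rows as deposited (open circles) and realigned (filled circles). The arrays of 4 h, 1 d and 2 d moved from at most 0.024 to at least 0.225, and the 4 d arrays stayed at 0.084 or below.

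At 4 h the highest ratios belonged to genes of liver secretion and metabolism. Alb, which encodes serum albumin, stood at a log2 ratio of 7.61 ± 0.58 (technical SD, 2 arrays). Apoh, a plasma apolipoprotein, stood at 6.32 ± 0.66, Cyp3a11, a drug-metabolising cytochrome, at 5.95 ± 0.53, and Serpinc1, antithrombin, at 5.68 ± 1.28. The hepatocyte list, which leaves these genes out, had a median of 1.16 over 6 genes, all above 0 and above the random lists (percentile 99.81). Pancreatic acinar genes were also above the pool, with a median of 0.97 over 11 genes (percentile 99.94). Ctrb1, the protease precursor chymotrypsinogen, was at 1.42 and Cela3b, an elastase, at 1.51. Interferon-stimulated genes lay below the random lists (median -0.51, 14 genes, percentile 2.21), as did dendritic cell markers (-0.71, 7 genes, 1.57). So did G2 and M phase genes (-0.45, 22 genes, 1.56), ribosomal protein genes (-0.34, 46 genes, 2.28) and stromal genes (-0.41, 25 genes, 2.41). Over all genes measured on each array, the G2 and M phase and stromal lists each lay above the median of the array on 1 of 2 arrays (means 0.19 and 0.14), and the other 3 lists below it on both. The lowest single genes were Kri1 at -4.23 ± 4.55, Nrf1 at -4.09 ± 3.65, Itga11 at -3.71 ± 3.73 and Notch1 at -3.47 ± 1.498. In all 1312 of 6160 genes were at least 2-fold from the pool (705 higher, 607 lower), and the median of all genes was -0.13.

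At 1 d the interferon genes were above the pool on both arrays. The interferon-gamma-induced GTPases and effectors, which act against intracellular pathogens, had a median of 1.505 over 5 genes, all higher (percentile 99.98). Tgtp1, a GTPase of this family, stood at 2.99 and Irf1, a transcription factor, at 2.46. The interferon-stimulated genes had a median of 0.99 with 13 of 15 higher, above all 10000 random lists, among them the antiviral genes Oas1a at 2.07 ± 0.46 and Mx2 at 1.71 ± 0.32 and the regulator Irf7 at 1.68 ± 0.53 (technical SD, 2 arrays). MHC class I presentation genes had a median of 0.79 with 9 of 10 higher (percentile 99.99), and Tap1, a peptide transporter, was at 1.46. With rows as deposited the interferon-gamma-induced list had a median of -0.102 and the interferon-stimulated list -0.114 at 1 d.

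Below the pool at 1 d were pancreatic acinar genes (median -2.79, 0 of 8 higher, below all 10000 random lists) and S phase genes (-0.41, 4 of 20 higher, percentile 0.3). G2 and M phase genes (-0.34, 6 of 20 higher, 0.86) and erythroid genes (-0.29, 8 of 23 higher, 1.63) were also below. Ctrb1 at -7.19 ± 0.05 and Cela3b at -5.12 ± 0.75 were the lowest genes, followed by the splicing factor Mbnl1 (-3.59 ± 1.49) and Rnf149 (-3.43 ± 0.89). The highest with the same sign on both arrays were Ankrd46 (3.95 ± 0.89), the steroidogenic factor Nr5a1 (3.53 ± 1.44), C2cd2l (3.50 ± 1.67) and the elongation factor Supt5 (3.44 ± 2.36). There were 883 of 6664 genes at least 2-fold from the pool (409 higher, 474 lower), and the median of all genes was -0.05. The median technical SD was 0.373 at 1 d, against 1.542 at 3 d and 1.207 at 9 d. The 2-fold counts of different times therefore do not compare the size of the response.

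**Figure D2:**
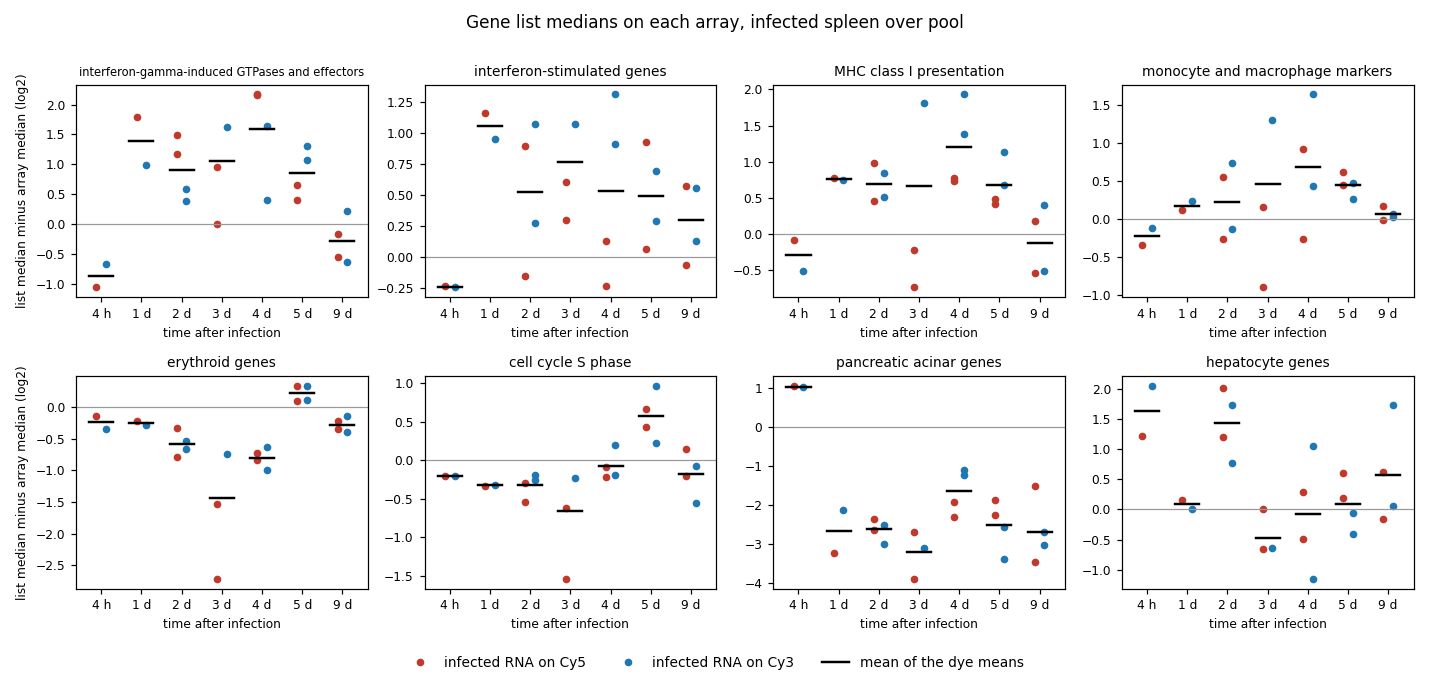
Each panel gives, for 1 gene list, its median log2 ratio minus the median of the array (y axis, log2) on every array against time after infection (x axis); red points have the infected RNA on Cy5, blue points on Cy3, and bars are means of the dye means. Acinar genes lie above 0 on both 4 h arrays and below 0 on all later arrays, and erythroid genes lie above 0 on the 4 arrays of 5 d only.

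Averaged over 4 h and 1 d, the genes of cell division and protein synthesis with a value on both dyes at every time fell below the pool. All 7 measured S phase genes were lower (median -0.39, adjusted p = 0.00705, and adjusted p = 0.658 with an estimated correlation). So were all 8 G2 and M phase genes (median -0.41, adjusted p = 0.00705, and 0.658 with an estimated correlation). Ccne1, the cyclin that starts DNA replication, stood at -0.66 ± 0.30 (mean of 2 time points, SE pooled over windows). Rrm2, a ribonucleotide reductase subunit, stood at -0.69 ± 0.33 and Mki67, a marker of dividing cells, at -0.66 ± 0.39. Ribosomal protein genes fell (33 of 36 lower, median -0.25, adjusted p = 0.00705, and 0.658 with an estimated correlation) against a median of -0.14 over all genes. Acinar genes fell (5 of 5 lower, median -1.80, adjusted p = 0.0282, and 0.658 with an estimated correlation). Their 4 h and 1 d medians lay on opposite sides of the pool, and without 1 d they were higher (adjusted p = 0.00604). The other 12 lists tested did not pass camera. Members of these 4 lists past the gene threshold numbered 0 over all genes and 0 adjusted over the list alone.

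In the early window 0 of 2156 genes passed limma's threshold (smallest adjusted p = 1). Of these, 25 had an unadjusted p under 0.05 where 107.8 are expected by chance, and the fit with arrays as replicates also found 0. The genes with the smallest p were Arid4a, a chromatin regulator (1.65 ± 0.45), and Rgcc, a cell cycle regulator (2.23 ± 0.61), on the higher side, and Dydc1 (-1.14 ± 0.30) and Hps6, of lysosome-related organelles (-1.44 ± 0.39), on the lower side. Without 4 h the adjusted p was 0.354 for G2 and M phase, 0.0559 for S phase and 0.417 for ribosomal genes, and without 1 d it was 0.56, 0.216 and 0.179. Without 3 d it was 0.1 for G2 and M phase and 0.177 for S phase, and without 4 d 0.0553 for S phase. Leaving out 4 h replicate 2 also ended calls (0.194 for G2 and M phase, 0.145 for S phase, ribosomal and acinar genes). So did leaving out 1 d replicate 2 (0.203, G2 and M phase), 3 d replicate 3 (0.11, S phase) or 1 d replicate 1 (0.101 for ribosomal and 0.107 for acinar genes). The acinar call was lost without 2 d (0.104), 3 d (0.177), 4 d (0.0856) or 5 d (0.0911). With a looser rule on missing values, chosen after seeing the data, all 4 calls were lost. The S phase list then had 22 genes (median -0.29, adjusted p = 0.906), the G2 and M phase list 23 (-0.20, 0.979), the ribosomal list 50 (-0.24, 0.345) and the acinar list 15 (-1.06, 0.0584).

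At days 2 to 3 the MHC class I pathway and part of the monocyte and macrophage genes rose while acinar, erythroid, ribosomal and part of the stromal genes fell. All 6 measured class I genes were higher (median 0.88, adjusted p = 0.0026, and adjusted p = 0.423 with an estimated correlation). Psmb8, an immunoproteasome subunit, stood at 1.09 ± 0.47 and H2-K1, a class I heavy chain, at 0.74 ± 0.32. The single-time medians lay inside the random lists, at 0.91 with 10 of 11 higher at 2 d (percentile 96.56) and 0.70 with 6 of 8 higher at 3 d (95.5), and at 3 d the list was above the median of the array on 1 of 3 arrays. Monocyte and macrophage markers rose, 5 of 8 higher (median 0.48, adjusted p = 0.0411, and 0.423 with an estimated correlation). The higher ones include F10, which is also in the hepatocyte list and stood at 1.36 at 2 d. They also include Ctsl, at -2.17 at 2 d and 2.56 at 3 d. Lgals3, a galectin of macrophages, stood at 1.05 ± 0.38 and Mpeg1, a pore-forming protein of phagocytes, at 1.04 ± 0.40. Oxidative phosphorylation genes rose, 21 of 32 higher (median 0.14, adjusted p = 0.0181, and 0.423 with an estimated correlation). Uqcrq of respiratory complex III stood at 1.498 ± 0.37. Interferon genes had 4 measured members per list and were not tested as lists here. Tgtp1 stood at 3.14 ± 0.79, Fcgr1, the high-affinity IgG receptor, at 2.29 ± 0.85, Stat2 at 1.42 ± 0.46 and Ifi27l2a at 1.33 ± 0.50. Cfb, complement factor B, stood at 2.58 ± 0.63.

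Acinar genes fell most (5 of 5 lower, median -4.12, adjusted p = 0.00243, and 0.423 with an estimated correlation). Ctrb1 stood at -6.48 ± 2.01 and Klk1, a tissue kallikrein, at -3.64 ± 0.89. Of these 5 genes, 0 passed over all genes and 5 adjusted over the list alone. Erythroid genes fell, 10 of 14 lower (median -1.01, adjusted p = 0.0427, and 0.455 with an estimated correlation). Sptb, red cell spectrin, stood at -2.36 ± 0.63 and Kel, a red cell membrane peptidase, at -1.68 ± 0.48. Stromal and extracellular matrix genes fell, 11 of 13 lower (median -0.56, adjusted p = 0.0411, and 0.423 with an estimated correlation). With the looser rule on missing values the stromal list had 29 genes, a median of 0.11 and an adjusted p of 0.721. At 2 d its median was 0.34 with 18 of 29 higher, and at 3 d -0.55 with 9 of 27 higher. Of the collagen genes, Col14a1 stood at -1.74 ± 0.32 and Col5a1 at -0.97 ± 0.31. Ribosomal protein genes fell, 30 of 36 lower (median -0.39, adjusted p = 0.0411, and 0.495 with an estimated correlation), against a median of -0.16 over all genes. Platelet markers did not pass camera, but 2 of 6 passed adjusted over the list alone (0 over all genes). Clec1b, a platelet receptor, stood at -1.46 ± 0.32 and Itga2b, the platelet integrin, at -1.37 ± 0.34. By fry the T cell list, of 5 genes, and the platelet list were lower (adjusted p = 0.0466 for each), and by fry none of the 7 lists above passed. With the looser rule the T cell list had 16 genes and a median of 0.17 (adjusted p = 0.95 by camera), and at 2 d its median was 0.91 with 9 of 13 higher.

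In limma's gene test at days 2 to 3, 0 of 2156 genes passed (smallest adjusted p = 0.29). An unadjusted p under 0.05 was found for 272, where 107.8 are expected by chance. The fit with arrays as replicates, whose error is technical spread only, found 104 (35 higher, 69 lower). Among the genes with the smallest p were Cfc1, a Nodal coreceptor (2.32 ± 0.44), Tmem268 (1.69 ± 0.32), Ppia, cyclophilin A (1.85 ± 0.38), and Hspb8, a small heat shock protein (1.52 ± 0.31), on the higher side. On the lower side they were Ttc13 (-2.55 ± 0.38), Gdf10 (-1.87 ± 0.36) and Postn, periostin (-1.48 ± 0.32). Without 2 d the adjusted p was 0.0905 for class I, acinar, monocyte and oxidative phosphorylation genes, 0.252 for erythroid, 0.135 for stromal and 0.711 for ribosomal genes. Without 3 d it was 0.106 for erythroid, 0.616 for monocyte, 0.0665 for oxidative phosphorylation and 0.456 for stromal genes. The oxidative phosphorylation call was also lost without 4 h (0.106) or 3 d replicate 3 (0.596), and with the looser rule over 53 genes (0.643). The monocyte call was lost with the looser rule over 12 genes (0.412), and without 4 h (0.107), 5 d (0.0537) or any of 6 arrays (0.0508 to 0.513). These were 3 d 3, which gave the highest value, 2 d 3, 3 d 1, 4 h 2, 5 d 3 and 5 d 4. The erythroid call was lost without 9 d (0.063) or any of 2 d 3, 3 d 1, 5 d 2, 5 d 3, 9 d 3 and 9 d 4 (0.0503 to 0.0783), and with each array centred on its median (0.0713). The ribosomal call was lost without any of 4 d 1, 4 d 4, 2 d 3, 5 d 3 and 9 d 3 (0.0527 to 0.1). The stromal call was lost without any of 4 d 1, 4 d 4, 2 d 2, 2 d 3, 3 d 1, 5 d 3, 5 d 4 and 9 d 3 (0.0531 to 0.144).

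The 2 days differed in several groups, which was not tested. At 2 d hepatocyte genes (median 1.62 over 10 genes, percentile 99.97) and acute phase and iron handling genes (1.79 over 10 genes, above all 10000) were above the random lists. Alb stood at 7.28 ± 0.17, Itih4, a liver plasma protein, at 7.40 ± 1.24, Lcn2, the siderophore-binding lipocalin, at 5.19 and Cp, ceruloplasmin, at 2.81 ± 1.27 (technical SD, 3 to 4 arrays). At 3 d Lcn2 was at -0.99 and acute phase genes had a median of -0.83 (percentile 3.53). Erythroid genes had a median of -0.32 at 2 d (8 of 24 higher, percentile 0.4) and of -1.11 at 3 d (6 of 22 higher, 0.01). At 3 d Hba-a1, alpha globin, was at -2.78 ± 0.78, Alas2, the first enzyme of erythroid haem synthesis, at -2.95 ± 0.43 and Slc4a1, the red cell anion exchanger, at -3.81. The interferon-gamma-induced list was at 1.12 at 2 d (percentile 96.73) and 1.14 at 3 d (97.68). Genes at least 2-fold from the pool numbered 2189 of 7312 at 2 d (1668 higher, 521 lower, and 1312 higher, 757 lower with arrays centred). At 3 d they numbered 2066 of 6075 (1055 higher, 1011 lower). Medians of all genes were 0.25 and -0.01.

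**Figure D3:**
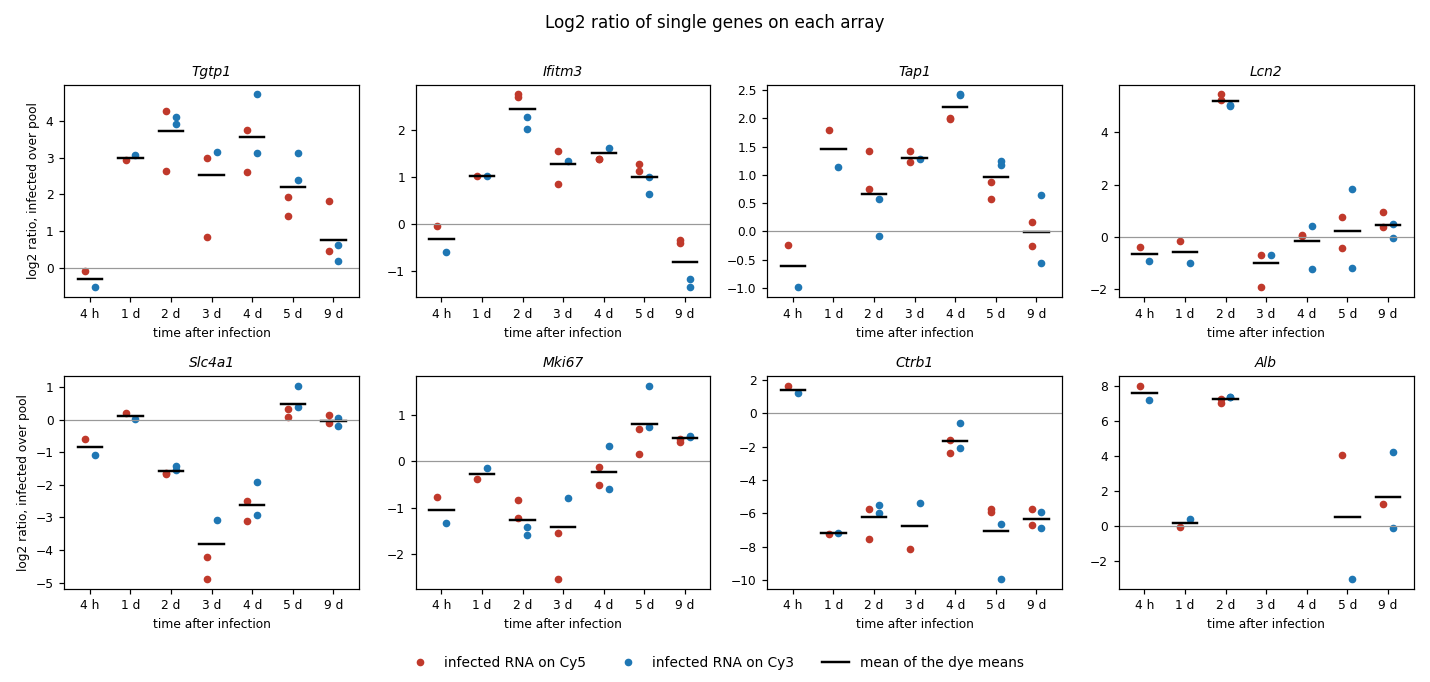
Log2 ratio of infected over pool (y axis) for 8 genes on every array against time after infection (x axis), with infected RNA on Cy5 in red and on Cy3 in blue and bars for the mean of the dye means. The bars of Tgtp1 lie between 2.21 and 3.74 from 1 d to 5 d and at 0.77 at 9 d. Those of Ctrb1 lie at 1.42 at 4 h and between -7.19 and -1.67 afterwards. Single arrays run from 0.83 to 4.72 for Tgtp1 from 1 d to 5 d, and from -9.94 to -0.61 for Ctrb1 after 4 h.

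At days 4 to 5 class I presentation and monocyte genes rose, the 7 S phase genes tested were above the pool, and acinar and erythroid genes were below it. All 6 class I genes were higher (median 1.08, adjusted p = 0.00478, and adjusted p = 0.484 with an estimated correlation). Of them, 0 passed over all genes and 4 adjusted over the list alone, with H2-K1 at 1.04 ± 0.32 and B2m, the class I light chain, at 1.12 ± 0.37. Monocyte and macrophage markers rose, 7 of 8 higher (median 1.02, adjusted p = 0.00478, and 0.484 with an estimated correlation). Lgals3 stood at 1.28 ± 0.38 and Ctsz, a lysosomal cathepsin, at 1.07 ± 0.33. S phase genes rose, 7 of 7 higher (median 0.55, adjusted p = 0.0257, and 0.484 with an estimated correlation). Ccne1 stood at 0.82 ± 0.30 and Pola2, of DNA polymerase alpha, at 0.94 ± 0.39. Ribosomal protein genes rose, 32 of 36 higher (median 0.38, adjusted p = 0.0257, and 0.534 with an estimated correlation), against a median of 0.19 over all genes. Erythroid genes fell, 10 of 14 lower (median -0.60, adjusted p = 0.0257, and 0.484 with an estimated correlation). Gfi1b, an erythroid repressor, stood at -1.36 ± 0.60, but this came from 5 d (-2.57, against -0.14 at 4 d). The single-time median of the list went the other way, from -0.58 at 4 d to 0.37 at 5 d. Acinar genes fell, 5 of 5 lower (median -3.31, adjusted p = 6.03e-05, and 0.484 with an estimated correlation). Klk1 stood at -2.87 ± 0.89. By fry the T cell list of 5 genes alone passed, as lower (adjusted p = 0.00452). Over all its genes measured on each array, it lay above the median of the array on 2 of 4 arrays at 4 d (mean -0.048). At 5 d it did so on 1 of 4 (mean -0.156).

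In limma's gene test at days 4 to 5, 0 of 2156 genes passed (smallest adjusted p = 0.359). An unadjusted p under 0.05 was found for 180, where 107.8 are expected by chance. The fit with arrays as replicates found 90 (63 higher, 27 lower). Tgtp1 stood at 2.88 ± 0.79, Mmp8, the neutrophil collagenase, at 1.95 ± 0.53, Nup153, of the nuclear pore, at 2.08 ± 0.35, Asns, asparagine synthetase, at 1.86 ± 0.34 and Txn1, thioredoxin, at 1.57 ± 0.35. Among the lower genes with the smallest p were the elongation factor Tcea2 (-3.08 ± 0.48), Otulin, a deubiquitinase (-2.07 ± 0.34), and Agrn, agrin (-2.24 ± 0.39). Of the T cell list, Gata3 stood at -1.93 ± 0.64. Without 5 d the adjusted p was 0.0677 for class I, acinar and ribosomal genes and 0.571 for S phase genes. Without 4 d it was 0.636 for erythroid genes, whose direction turned, and 0.365 for ribosomal genes. No single time point or array ended the monocyte call. The S phase call was lost without 4 d 2 (0.0809), 2 d 4 (0.0653), 3 d 1 (0.0614) or 5 d 3 (0.0509). With the looser rule it was lost over 22 genes (median 0.38, adjusted p = 0.33). The erythroid call was lost without 9 d (0.0734) or any of 4 d 4, 2 d 2, 2 d 4, 3 d 1, 5 d 2, 5 d 4 and 9 d 1 (0.0511 to 0.127). The ribosomal call was lost without 4 h (0.0573), 1 d (0.0637) or any of 4 d 2, 4 d 4, 2 d 4, 3 d 1, 3 d 2, 5 d 1, 5 d 3 and 9 d 2 (0.0517 to 0.14), and with the looser rule over 50 genes (0.104).

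At 4 d class I genes had a median of 1.44 and monocyte markers of 1.18 (10 of 14 higher), both above all 10000 random lists, and the monocyte list lay above the median of the array on 3 of 4 arrays. Tyrobp, a myeloid signalling adaptor, was at 2.99 ± 0.84. Irf1 stood at 3.20 and Tap1 at 2.20. The interferon-gamma-induced list, to which Irf1 belongs, had a median of -0.37 at 4 d with 4 of 9 higher (percentile 12.48), and of 1.42 on Cy5 but -0.91 on Cy3. Over all its genes measured on each array, it lay above the median of the array on 4 of 4 arrays (by 0.41 to 2.17). At 5 d its median was 1.14 with 5 of 7 higher (percentile 99.91). Erythroid genes had a median of -0.58 (7 of 26 higher, percentile 0.21), with Hba-a1 at -3.02 ± 0.84 and Alas2 at -2.83 ± 1.14. At 5 d the erythroid median was 0.37 (16 of 28 higher, percentile 98.56), Hba-a1 was at -0.25 ± 0.33 and Slc4a1 at 0.47. S phase genes had a median of -0.018 at 4 d (13 of 26 higher, percentile 38.88) and of 0.55 at 5 d (17 of 24 higher, percentile 99.85). At 5 d Ccne1 (0.94 ± 0.35), Rrm2 (0.91 ± 0.66) and Mcm2, a replication helicase (0.76 ± 0.35), were higher on 4 of 4 arrays. Acinar genes stood at a median of -1.56 at 4 d and -2.16 at 5 d, below all random lists. Genes at least 2-fold from the pool numbered 2086 of 8420 at 4 d (1000 higher, 1086 lower) and 1689 of 8624 at 5 d (824 higher, 865 lower), with a median of all genes of 0.04 and 0.03.

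By day 9 the acinar genes were the only list of the 16 that passed camera: they fell, 5 of 5 lower (median -3.99, adjusted p = 0.00125, and adjusted p = 0.999 with an estimated correlation). Klk1 stood at -4.43 ± 1.26 and Ctrb1 at -6.31 ± 2.85 (1 time point, SE from the spread in the other windows). Class I genes had a median of 0.08 with 3 of 6 higher, monocyte markers 0.18, erythroid genes 0.05 and S phase genes -0.24, against -0.05 for all genes, and none of these 4 lists passed. Tgtp1 was at 0.77, Tap1 at -0.01 and Ifitm3, an interferon-induced membrane protein, at -0.81. Interferon-stimulated genes, over all those measured at 9 d, had a median of 0.96 with 13 of 17 higher (percentile 98.1), while the median of all genes measured then was 0.29. Against the median of each array they ran from -0.067 to 0.57 (mean 0.30, above on 3 of 4 arrays). Markers of splenic macrophages had a median of 0.25 at 9 d with 4 of 7 higher (percentile 45.34), at -1.08 on Cy5 and -0.20 on Cy3. Over all its genes measured on each array, the list lay below the median of the array on 4 of 4 arrays (mean -0.72). Among the lower ones were Axl, a receptor for dying cells, at -1.71 ± 0.51 and Vcam1, an adhesion molecule, at -1.60 ± 0.63.

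In limma's gene test at day 9, 0 of 2156 genes passed (smallest adjusted p = 0.229). An unadjusted p under 0.05 was found for 148, where 107.8 are expected by chance. The fit with arrays as replicates found 6. The smallest p belonged to Tor1a, torsin (3.98 ± 0.58), Tent5a, a poly(A) polymerase (3.50 ± 0.48), and Ppp2cb, of phosphatase 2A (3.02 ± 0.42). On the lower side it belonged to Capn10, a calpain (-3.50 ± 0.53), and Ddx56, an RNA helicase (-2.92 ± 0.55). Without 9 d replicate 2, Tent5a passed (log2 ratio 4.97), as the only gene in that setting. Scaling the arrays ended the acinar call (adjusted p = 0.154). Genes at least 2-fold from the pool numbered 2574 of 8014 (2043 higher, 531 lower, and 1567 higher, 774 lower with arrays centred).

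Between days 2 to 3 and days 4 to 5, S phase genes rose by a median of 1.32 with 7 of 7 higher (adjusted p = 0.00901, and adjusted p = 0.83 with an estimated correlation). Ribosomal protein genes rose by 0.70 with 34 of 36 higher (adjusted p = 0.00461, and 0.95 with an estimated correlation), against a shift of 0.35 over all genes. With the looser rule the S phase list had 22 genes, a median of 0.67 and an adjusted p of 0.465. Of the 7 S phase genes 0 passed over all genes and 3 adjusted over the list alone. Rrm2 differed by 1.57 ± 0.47 and Ccne1 by 1.36 ± 0.42. Rpl30, of the large ribosomal subunit, differed by 1.28 ± 0.49. No list passed between the early window and days 2 to 3 (lowest adjusted p = 0.0563) or between days 4 to 5 and day 9 (0.29). The S phase difference was lost without 4 h (0.0595), 2 d (0.368), 5 d (0.268) or 2 d replicate 2 (0.0553), and the ribosomal one without 2 d (0.383) or 4 d (0.0555).

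Genes past limma's threshold numbered 0 of 2156 in each difference between windows and in the F test of any difference. Unadjusted p under 0.05 was found for 84 genes between the early window and days 2 to 3, for 207 between days 2 to 3 and 4 to 5, for 127 between days 4 to 5 and day 9, and for 128 in the F test, where chance gives 107.8. The fit with arrays as replicates found 9, 8, 1 and 25. Among the genes with the smallest p were Stom, stomatin of the red cell membrane (2.20 ± 0.42), and Ttc13 (-2.52 ± 0.54) in the first difference. In the second they included Nup153 (2.92 ± 0.49), Wbp1 (2.61 ± 0.51), Lrrc39 (-4.46 ± 0.59) and St7 (-4.47 ± 0.75), and in the last Tor1a (4.77 ± 0.71), Clvs1 (3.88 ± 0.57) and Coa4 (-3.73 ± 0.68). None passed the threshold.

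Taking the arrays as replicates measures technical spread alone, and calls say only that a gene differed between these RNA samples and the pool. At days 2 to 3 Slc4a1 was lower by this fit (-2.79 ± 0.22, adjusted p = 1.3e-07), as were Alas2 (-1.88), Hba-a1 (-1.98), Mki67 (-1.43), Ctrb1 (-6.48) and Cela3b (-4.29). Tgtp1 (3.07 ± 0.32), Lcn2 (2.06), Fcgr1 (1.99), Stat2 (1.34), Tap1 (0.98) and Psmb8 (0.98) were higher. The Lcn2 value came from 2 d alone (5.19), as at 3 d it was at -0.99. At days 4 to 5 Tgtp1 (2.88), Irf1 (2.25), Mmp8 (1.95), Tyrobp (1.61), Tap1 (1.59), Psmb8 (1.42), B2m (1.12) and H2-K1 (1.04) were higher and Ctrb1 (-4.37), Hba-a1 (-1.53) and Slc4a1 (-1.07) lower. The values of Hba-a1, Slc4a1 and Tyrobp came mainly from 4 d. On the probes of this fit Hba-a1 stood at -3.02 at 4 d and -0.049 at 5 d, Slc4a1 at -2.61 and 0.47, and Tyrobp at 2.99 and 0.06. At day 9 the calls included the acinar genes Ctrb1 (-6.31), Klk1 (-4.26), Pnliprp1 (-3.90) and Cela3b (-3.62). Between days 2 to 3 and days 4 to 5, Slc4a1 (1.72), Mki67 (1.72), Cd24a (1.63) and Tyrobp (1.86) rose, Slc4a1 through 5 d and Tyrobp through 4 d, and between days 4 to 5 and day 9 Ifitm3 fell (-2.02). A fit with the replicate number as a block estimated ratios against the pool for replicate 1 rather than over all arrays. Its counts against the pool are therefore not comparable with those above, while its differences between windows are. It gave 2 genes at days 2 to 3, 2 at days 4 to 5 and 0 at day 9. For differences it gave 0 between the early window and days 2 to 3, and 9 between days 2 to 3 and days 4 to 5. It gave 1 between days 4 to 5 and day 9 and 15 in the F test.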

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

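The tests of acinar, hepatocyte and erythroid genes, and of arrays less their own median, were chosen only after the result was seen, except the islet gene test; the differences between windows were tested as fixed beforehand.

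Pancreatic acinar genes lay below the pool from 1 d on: their median was below the random lists at 6 of 6 times, while at 4 h it was above them (0.97). Wrong gene names from the realigned rows are argued against, since at 5 d and 3 d, where no row was moved, the medians were -2.164 and -2.752. Pancreatic RNA in the control pool may be the cause but cannot be told apart from other causes here. The prediction was that all 7 times lie below the random lists, and 6 of 7 did, which is the pattern itself. It holds only if no infected sample carried pancreatic RNA of its own, so the 4 h value does not decide the question. Islet RNA coming with acinar RNA in the pool was not seen. The islet list lay below the random lists at 0 of 6 times, with only 5 to 8 islet genes measured. A change in acinar transcripts brought by infection stays open and untested.

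Hepatocyte genes lay above the random lists at 2 d (median 1.618) and 4 h (1.156), and inside them at the other 5 times (medians -0.49 to 0.83, percentiles 5.3 to 89.4). An acute phase response of spleen cells is argued against for 4 h, where the acute phase list had a median of -0.161 (percentile 44.92) while hepatocyte genes outside that list stood at 1.156 (99.69); at 2 d both lists were high and this stays open. Wrong names from the realigned rows are argued against, since moving the names by 2 to 600 rows along the realigned table gave a lower median at 99.92% of 1197 offsets at 2 d and of 1181 at 4 h (1 offset as high at each time), although the check on probe pairs of the realigned arrays alone found nothing (0.018 against 0.055 elsewhere). Liver RNA in the 4 h and 2 d samples is a candidate source that was not tested apart from the pattern. The list written without the liver genes already seen was above the random lists at both times, which is the pattern itself. Alb, the most abundant liver transcript and 1 of the genes seen first, stood at 7.61 and 7.28. The list has 17 genes on the array, 2 of them also in another list, and 6 and 10 were measured at these times.

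Erythroid genes lay below the pool at 3 d and 4 d, and at 4 d the median less that of all genes was -0.756 on Cy3 arrays (percentile 0.45) and -0.475 on Cy5 arrays (2.38), outside the random lists on both, which argues against dye bias there, although 4 d replicate 3 was itself placed through arrays of its dye. At 3 d the median over the mean of both dyes was -1.113 (percentile 0.01). A dye bias of equal size cancels in this mean, so such a bias could not have produced it. It is the value that raised the pattern, however, and so no separate test. The list was below on both dyes, at -1.916 on Cy5 and -0.65 on the 1 Cy3 array, but the latter lay inside the random lists (percentile 6.31), so a bias of unequal size stays open. The bound was changed after these values were seen: an earlier one, -0.5 on both dyes, would have excluded dye bias at 3 d and left it open at 4 d. A lower share of erythroid cells may also be the cause but cannot be told apart here, as 72.7% of the erythroid genes (16 of 22) were lower at 3 d, between the bounds set for and against it.

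Among 92 groups of 4 arrays, 5 had 1 array far from the other 3, where chance gives 4.6. With each array's own median taken off, 0 of these 5 stood apart, and 3 others of 80 such groups did, where chance gives 4. B cell markers in 9 d replicate 1 had a median log2 ratio of 0.715 against -0.400 to -0.301 in the others. MHC class I presentation in 9 d replicate 4 was at -0.566 against 0.271 to 0.412. Acute phase genes in 5 d replicate 4 were at -0.103 against 0.726 to 0.796. Erythroid genes in 4 d replicate 4 were at -1.866 against -0.527 to -0.340. Heat shock proteins in the same array were at -1.339 against 0.386 to 0.589, and the median of all its probes was -0.868, against which they were at -0.471 and the erythroid genes at -0.997.

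In camera's test of the difference between days 2 to 3 and days 4 to 5, S phase genes differed with an adjusted p of 0.00901 (0.83 with an estimated correlation) and ribosomal protein genes with 0.00461 (0.95). The S phase difference was lost without 4 h (0.0595), 2 d (0.368), 5 d (0.268) or 2 d replicate 2 (0.0553), and the ribosomal one without 2 d (0.383) or 4 d (0.0555).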

How the results depend on the processing

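Rows as deposited, floor values kept, Cy3 arrays turned, days 3, 4, 5 and 9 only, the looser missing-value rule for lists, and lists without acinar and hepatocyte genes were chosen after seeing the data; the other alternatives were fixed beforehand. Over the alternatives run for them, the 20 list calls gave 826 values, of which 621 kept direction and threshold, 192 kept direction but were not past it and 13 turned. The named genes were run with arrays centred or scaled, plain means, 5 and 3 windows, arrays as replicates and each array left out, and gave 2203 values with 0 turned and 18 newly past the threshold. They were not run with time points left out, rows as deposited, floor values kept or Cy3 arrays turned. The 44 list medians outside the random lists gave 275 values, 189 within 1 SD, 48 further away and 38 turned. List calls numbered 20 of 112 tests. They numbered 0 with an estimated correlation, 3 by fry with 0 shared and 0 of 42 with rows as deposited. They numbered 2 with Cy3 arrays turned, 7 with days 3, 4, 5 and 9 only (7 shared) and 12 without acinar and hepatocyte genes (12 shared, 4 calls of other lists lost). They ran from 11 to 25 leaving out 1 time point (11 without 2 d) and from 11 to 25 leaving out 1 array (11 without 3 d replicate 1, 12 without 4 d replicate 4, 13 without 9 d replicate 3). Centring the arrays gave 19, all shared. The looser rule gave 14 of 217 (10 shared), with adjusted p of 0.0584 to 0.979 for the 10 lost. Floor values kept gave 14 (14 shared, the 6 lost at 0.0513 to 0.0626), and 3 windows gave 14 of 48 (9 shared). Causes were not tested, except that 42 tests remained with rows as deposited because fewer genes had values.

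With arrays as replicates the genes past the threshold numbered 104 at days 2 to 3, 90 at days 4 to 5, 6 at day 9, 9, 8 and 1 in the successive differences and 25 in the F test. With the replicate block they numbered 2 at days 2 to 3, 2 at days 4 to 5, 0 at day 9, 0 between the early window and days 2 to 3, 9 and 1 in the later differences and 15 in the F test. In that fit the ratios against the pool were those of replicate 1, so its counts against the pool are not comparable with the ones before. The 58 pairs of arrays of different times with the same number had a median r of -0.067 (-0.237 to 0.248). For 166 other pairs it was 0.029 (-0.254 to 0.254), so no pairing by number was seen. As the numbers largely follow the dye, whose effect was taken out first, pairing is not excluded. Floor values kept gave 2 genes at days 2 to 3 and 14 at day 9. Leaving out 1 array gave 0 to 1 at day 9 (1 without 9 d replicate 2).

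Genes at least 1.5-fold from the pool numbered 2593 at 4 h, 1863 at 1 d, 3805 at 2 d, 3382 at 3 d, 4066 at 4 d, 3533 at 5 d and 4192 at 9 d. With a value in all 23 arrays (581 genes) those at 2-fold numbered 30, 10, 66, 124, 112, 28 and 37, as fewer genes were counted. Scaling gave 2097 at 1 d and 1096 at 3 d, where the unscaled counts at 2-fold were 883 and 2066, so the order of these 2 times reversed.

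With Cy3 arrays turned, list calls changed direction, with adjusted p of 0.806 (MHC class I, monocyte and oxidative phosphorylation at days 2 to 3), 0.543 (G2 and M phase early, ribosomal difference), 0.987 (S phase and monocyte at days 4 to 5), 0.476 (S phase early), 0.941 (erythroid at days 4 to 5), 0.279 (acinar at day 9) and 0.0323 (ribosomal at days 4 to 5). Leaving out 1 time point, acinar early ran from 1.97e-22 to 0.177 and turned without 1 d (0.00604), and erythroid at days 4 to 5 ran from 0.00167 to 0.636 and turned without 4 d (0.636). List medians that changed sign with Cy3 arrays turned were, at 4 h, G2 and M phase 0.28, dendritic 0.086, hepatocyte -0.22, interferon-stimulated 0.013, ribosomal 0.27 and stromal 0.18. At 1 d they were MHC class I -0.028, erythroid 0.044 and interferon-stimulated -0.12. At 2 d they were B cell 0.14, T cell -0.17, acute phase -0.014, erythroid 0.059, acinar 0.17 and ribosomal 0.24. At 3 d they were interferon-gamma-induced -0.014, acinar 0.41 and stromal 0.43. At 4 d they were erythroid 0.23, monocyte -0.20, cytokines -0.12 and ribosomal -0.19. At 5 d they were heat shock -0.078, interferon-gamma-induced -0.052 and acinar 0.31. At 9 d they were interferon-stimulated -0.017, acinar 1.04 and ribosomal 0.079. With rows as deposited the medians that changed sign were B cell 2 d 0.88, dendritic 4 h 0.27, erythroid 2 d 0.20, hepatocyte 4 h -0.012, interferon-gamma-induced 1 d -0.102, interferon-stimulated 1 d -0.114, acinar 2 d 0.73, ribosomal 2 d 0.23 and 9 d 0.002. With a value in all 23 arrays, ribosomal genes at 9 d were at 0.029. The number of arrays and their low correlation limit all values; signal over background was not analysed here.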

Other observations

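Single-time values here were planned, while the looser missing-value rule for lists was chosen after the data were seen. At 2 d genes of the unfolded protein response and the endoplasmic reticulum were above the random lists (median 0.94, 15 of 17 higher, percentile 98.88), in the sample where hepatocyte genes had a median of 1.62 and Alb stood at 7.28, with Dnajb11, a luminal co-chaperone, at 2.16 ± 0.62 and Hspa5, the chaperone BiP, at 1.14 ± 0.25 (technical SD). T cell markers had a median of 0.91 at 2 d (9 of 13 higher, 97.6), but 0.063 on Cy5 and 0.78 on Cy3, and against the median of each array they ran from -0.71 to 0.63 (mean 0.097, 4 arrays). Of the 5 T cell genes tested at days 2 to 3, 4 were lower. B cell markers were below the random lists at 2 d (-0.47, 3 of 14 higher, 0.41). At 4 d proinflammatory cytokines and chemokines had a median of 0.90 with 9 of 10 higher (percentile 99.72), including the chemokines Ccl5 at 1.33 ± 0.68 and Ccl9 at 1.33 ± 0.72, and plasma cell and antibody secretion markers were at -0.81 with 1 of 7 higher (2.1). At 5 d heat shock proteins (0.56, 12 of 17 higher, 99.49) and cholesterol synthesis genes (0.46, 12 of 14 higher, 97.57) were above the random lists. Adipose genes, as a marker of attached fat, stayed inside them at all 7 times (highest at 3 d, 0.69, 96.98).

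With the looser rule, under which interferon lists had enough genes for camera, interferon-stimulated genes were higher in the early window (adjusted p = 0.0204, with a single-time median of -0.51 at 4 h, percentile 2.21, and of 0.99 at 1 d), at days 2 to 3 (0.024) and at days 4 to 5 (0.0375), and interferon-gamma-induced genes at days 4 to 5 (0.0397). At 4 d alone the latter list had a median of -0.37 over 9 genes, and of 0.50 (percentile 91.84) with rows as deposited, while over all its genes measured on each array it lay above the array's median on 4 of 4 arrays (mean 1.59). None of these 4 calls held with an estimated correlation. The same rule kept 10 of the 20 list calls and ended the other 10, among them all 4 of the early window. Il1b, the inflammasome cytokine, stood at -0.75 at 4 h, between 1.16 and 1.56 from 1 d to 4 d, and at 0.06 at 5 d. S100a8, a neutrophil calcium-binding protein, stood at -1.56 at 4 h and 1.12 at 9 d.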
